A study of Mus musculus with 6 samples.

How the data were processed

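The samples were CD45-positive, CD4-positive cells sorted from mouse liver on day 14 after bone marrow and splenocyte transfer, profiled by droplet-based 5' single-cell RNA sequencing. Per the labels, 3 mice were syngeneic (Balb/c donor cells in Balb/c recipients) and 3 were allogeneic (B10.D2 donor cells in Balb/c recipients, a model of chronic graft-versus-host disease). Recipients had been irradiated with 850 cGy in 2 doses 3 hours apart and received splenocytes with bone marrow cells. The labels give 6000 loaded cells, viability above 82% and a sort purity of 95%.

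The submitters' processing notes name Cell Ranger 3.0.2, Seurat and the mouse build mm10. Which role each step played, how cells were filtered, how doublets and free RNA were treated and how clusters were made are not given in the sources used here. The 2 deposited tables hold the authors' own results per cluster. The cells of the 3 mice of a group are pooled in both of them. One table compares the groups within each of 16 numbered clusters. The other lists marker genes for 17 clusters, each compared with all other cells, separately in both groups.

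Per the file headers, the authors deposited for each gene and cluster an average log fold change, which was read as a natural log because Seurat versions with that column name used this base. The base is not stated in the table and could not be settled from the values, so log fold changes are printed as deposited and no linear fold is given. The deposited fraction columns give the share of cells of a cluster in which a transcript was seen, and are printed as percentages. The deposited p-value columns were computed by the authors across cells. They hold a raw p-value and one adjusted by Bonferroni, which equals the raw value times 15676 up to a maximum of 1. Other deposited columns give cluster numbers and names. The table of the group comparison lists a gene only from an absolute log fold change of about 0.25 and from about 10% of cells in one of the groups.

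The headers do not name the numerator of the group comparison. In all 2456 gene and cluster pairs shared with the marker table, the first detection share equalled the syngeneic and the second the allogeneic share exactly. Of 518 pairs with an absolute log fold change over 1, 514 moved with the detection share. Signs were therefore turned, so that a positive log fold change means higher in allogeneic cells. Repeated rows of the same gene and cluster were dropped, 23 of 12682 in the group comparison and 36 of 10346 in the marker table. No column of values per mouse was used, so no test across mice was made. Depth per mouse and molecules per cell are not used here, and the tables do not state cells per cluster. The deposited shares of a small cluster fall on few values, so the fewest cells, up to 500, that can give every share of a cluster and group within 0.05 points were found for 17 of 33 combinations, in an analysis added after the data were seen. For syngeneic and allogeneic cells in turn they were 389 and 16 in cluster 10, 61 and 302 in cluster 11, 202 and 125 in cluster 12, 14 and 131 in cluster 13, 98 and 34 in cluster 14 and 38 and 90 in cluster 15. Syngeneic cells were 343 in cluster 6, 216 in cluster 8, 145 in cluster 9 and 38 in cluster 16, and allogeneic cells 286 in cluster 7. Detection shares are printed without an interval, as mice are pooled in them.

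A call is a gene and cluster pair past the deposited adjusted p-value threshold of 0.05. Cells are not replicates, so a call says that the pooled cells of both groups differed, not that 3 mice differed from 3 others. The groups also differ in donor strain, so treatment and strain cannot be told apart. Fixed before the data were examined were 37 gene lists, the rule for named genes and the alternatives. For each list the median log fold change over the clusters listing a gene was taken, then the median over genes. Its percentile was found among 10000 random lists of the same size matched in 10 bins of detection. A list outside the central 95% is said to stand apart, and lists with under 3 listed members have no percentile. Of the 33 lists with a percentile 22 stood apart, 17 at the high end and 5 at the low end. Standing apart was thus common and does not single out a list. Because the table leaves out small changes, random medians fall mostly outside the gap around 0, and a percentile reflects how many members lie on each side. Clusters 10, 11, 13, 14 and 15, with few cells in a group, listed 1410, 860, 2467, 848 and 1363 of the 12659 pairs. They made 93, 29, 178, 30 and 40 of the 5737 calls. Only 2416 of the 5196 genes had a call, so random lists draw many genes without one. Tested on simulated data, 7% of 200 unchanged random lists of 20 genes stood apart, against 8.5% with 0.2 added to the log fold change and 37.5% with 0.4 added, over 5196 genes. A separate simulation of 5196 genes gave changed genes p-values far below the threshold. Their 100% recovery by Benjamini-Hochberg adjustment was thus fixed in advance, and 9 unchanged genes were called. It checks how the adjustment was computed and says nothing about the calls. Counts adjusted over the list alone apply Benjamini-Hochberg adjustment to the raw p-values of the listed pairs of that list.

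Named genes are the 12 higher and 12 lower in the most clusters, the 3 highest and 3 lowest calls per cluster, all glycolysis genes, and up to 4 genes per other list with the most calls. A cluster kept its number and is called by a cell type with the ending "-like" only where at least 3 genes of a marker list were higher in it in both groups and its leading genes did not go against that. Some genes that the rule takes are not reported here. The leading genes were the 5 with the highest of the smaller log fold changes of both groups. Gene positions come from GENCODE M21 on GRCm38, the assembly also called mm10, whose symbols matched 5158 of the 5196 genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used. The alternatives were other thresholds, other filters, centring, leaving out each cluster, and, added after the data were seen, the T cell clusters alone, leaving out genes called alike in myeloid cells, and another matching of random lists. The cluster listed in syngeneic cells alone was left out of every comparison between groups.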

Results

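CD4-positive immune cells of the liver were compared between allogeneic and syngeneic recipients 14 days after transplant, in 3 mice per group. The comparison asks how T cells in the liver differ when donor cells meet a foreign host, with glucose metabolism named in the study's title. Values below are the authors' per-cluster results over the pooled cells of each group. Spread between mice is not known, and log fold changes are allogeneic minus syngeneic, read as natural logs although the base is not stated. Donor strain differed with the group in every comparison.

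Most of the 16 compared clusters carried T cell markers. Cluster 0 was cytotoxic effector-like, with Cst7, Fasl, Gzma, Gzmk, Klrd1, Nkg7 and Prf1 higher in it in both groups, and it was led by the chemokine genes Ccl4, Ccl5 and Ccl3. Cluster 1 was Th1-like (Cxcr3, Cxcr6 and Hopx), cluster 3 was Treg-like (12 markers, among them Foxp3, Ikzf2 and Ctla4) and cluster 7 was naive-like (13 markers, among them Ccr7 and Lef1). The name of cluster 1 rests on those 3 genes alone, without Ifng or Tbx21. Zbtb16 was seen in 34.5% and Il4 in 48.5% of its syngeneic cells, so it need not hold Th1 cells alone. Clusters 5, 6 and 9 carried 16, 31 and 19 cell cycle genes, and cluster 14 carried 17 type I interferon response genes. Clusters 2 (led by Ifitm1, Ifitm2 and Vim) and 4 (led by Tcf7, Slamf6 and Itgb1) stayed unnamed. Cluster 2 had 3 Th1 markers (Bhlhe40, Ccr2 and Il18r1), as many as cluster 1. It also had 3 naive and central memory markers (Il7r, Klf2 and S1pr1), and was given neither name. Other cells were present too. Not all need have escaped the sort, as Cd4 was seen in 71.2% of syngeneic and 50% of allogeneic cluster 10 cells. Cluster 8 was macrophage-like (11 markers, led by C1qb, C1qc and Apoe), cluster 10 dendritic-like (7 markers, among them Siglech, beside 5 B and plasma cell genes) and cluster 15 neutrophil-like (8 markers, led by S100a9 and S100a8). Cluster 12, led by Lyz2 and Cd74, had myeloid markers of more than one kind and was not named, and neither were cluster 11 with 1 conserved marker, Atp5k, and cluster 13 with 5, Tyrobp, Gpx1, Alox5ap, Spi1 and Fcer1g. By detection Atp5k does not mark cluster 11. It was seen there in 19.7% of syngeneic and 20.2% of allogeneic cells, against 64.7% and 71.9% of other cells. Over all clusters 3034 markers were shared by both groups, counted from the authors' deposited table.

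Between the groups, 5737 gene and cluster pairs of the authors' deposited table were called, 2599 higher and 3138 lower in allogeneic cells, so 45.3% were higher. They came from 2416 genes, of which 776 were called higher alone, 1354 lower alone and 286 in both directions in different clusters. The macrophage-like cluster 8 had 1118 calls and cluster 12 had 730, against 453 in cluster 0 and 489 in cluster 3. Clusters 11, 14 and 15 had 29, 30 and 40 calls. In cluster 13, 170 of 178 calls were lower. In the 10 T cell clusters (0 to 7, 9 and 14), a set chosen after the data were seen, 1718 pairs were higher and 1831 lower.

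**Figure D1:**
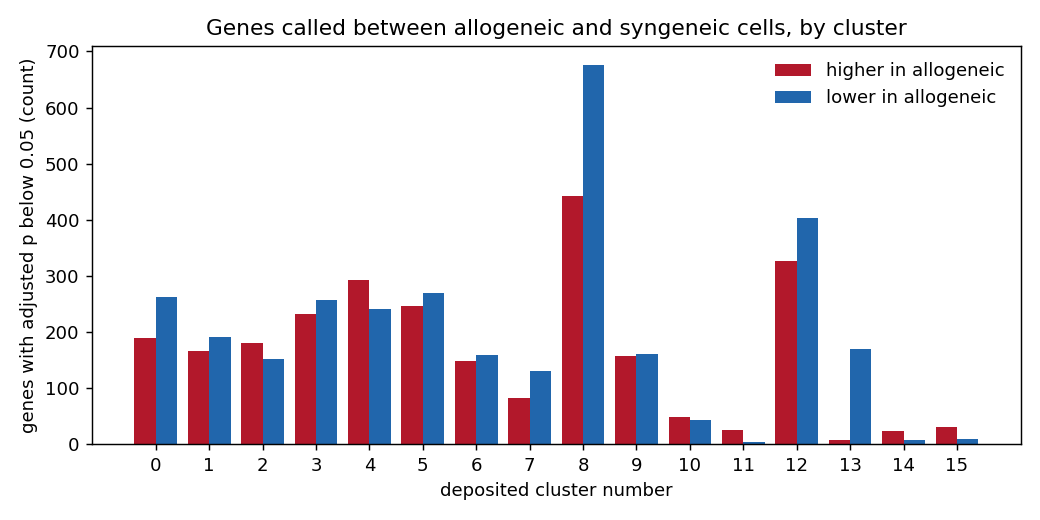
Bars give the number of genes called higher (red) or lower (blue) in allogeneic than in syngeneic cells in each deposited cluster, at an adjusted p-value threshold of 0.05 across cells. Cluster 8 has the tallest bars, with 442 genes higher and 676 lower.

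A set of 97 genes changed in the same direction in at least 8 of the 16 clusters with no call the other way, 57 higher and 40 lower in allogeneic cells. Ly6a, which encodes the surface protein Sca-1, was higher in 15 clusters. Its share of positive cells in the authors' deposited table went from 4.3% to 95.1% in cluster 0, from 12.2% to 97.6% in cluster 7 and from 6.9% to 91.8% in cluster 8. The class I MHC gene H2-Q7 was higher in 14 clusters, the chemokine gene Ccl5 and the antiviral gene Apobec3 in 13, and Lag3, an inhibitory receptor gene, Gm42031, AW112010 and Trim12a in 12. Tigit, another inhibitory receptor gene, was among those higher in 11. Sfi1, a centrosome gene, was lower in 14 clusters, the protease gene Ctse in 12, and Txnip, Tpm3-rs7 and Ocel1 in 11. Txnip encodes a protein that restrains glucose uptake. The median log fold change over called clusters in the authors' deposited table was 2.53 for Ly6a, 1.21 for H2-Q7, 1.68 for Ccl5, -0.92 for Sfi1, -0.64 for Ctse and -0.65 for Txnip. At 12 or more clusters, which is 75% of them, 11 of the 97 genes remained, 9 higher and 2 lower. On GRCm38, Ly6a lies on chromosome 15 from 74994877 to 74998031, H2-Q7 on chromosome 17 from 35439155 to 35443773, Sfi1 on chromosome 11 from 3131850 to 3193463 and Txnip on chromosome 3 from 96557957 to 96561883. All are annotated as protein-coding genes. Ly6a and H2-Q7 belong to the list of strain-variable loci, in which 38 pairs were higher and 22 lower, with a median of -0.29 at percentile 40.7. Strain variants can go either way, so this signed median cannot measure a strain effect. Of the 79 listed pairs of this list 60 were called, many of them of Ly6a and H2-Q7, against 5737 of 12659 over all genes.

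**Figure D2:**
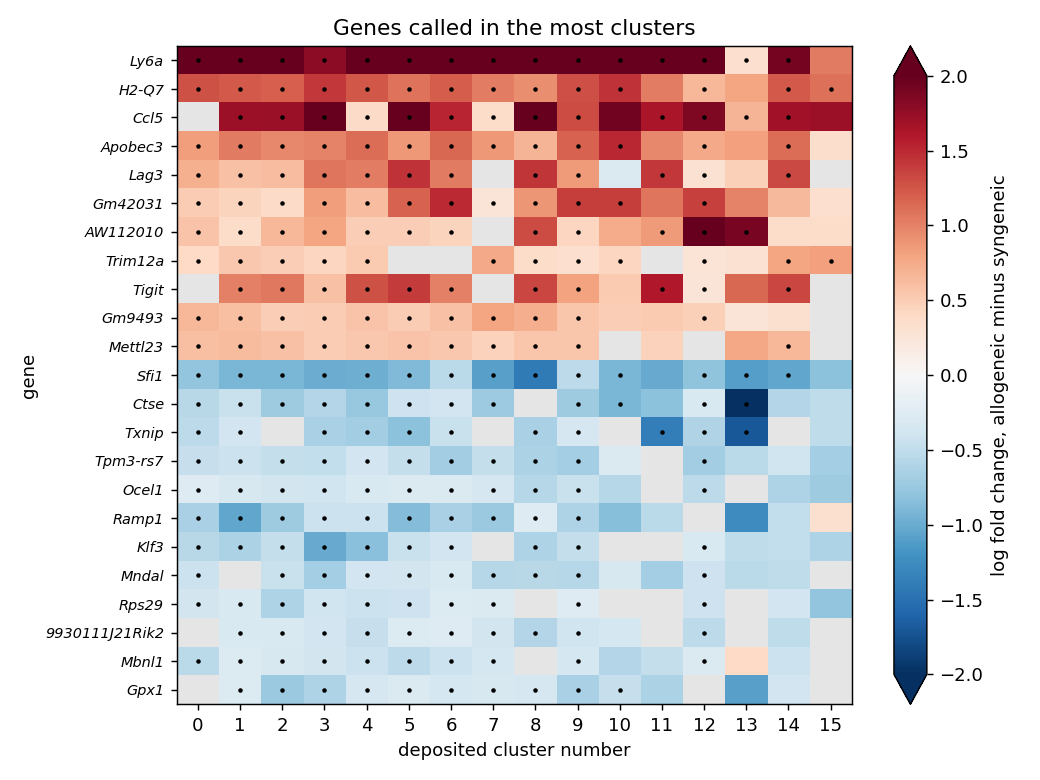
Colour gives the authors' log fold change, allogeneic minus syngeneic, of 11 genes called higher and 12 called lower in the most clusters, with a dot for each call and grey where the gene is not listed. Colours saturate beyond the ends of the scale, and Ly6a is called in 15 clusters.

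Glycolysis genes were higher in allogeneic cells. Of the 21 genes, 10 were called higher in at least 1 cluster, 2 lower and 9 not called, giving 35 pairs higher and 2 lower. Adjusted over the list alone, 49 were higher and 8 lower. Gapdh was higher in 10 clusters, Aldoa in 7, Pkm and Tpi1 in 4, Ldha, Pgk1, Pgam1 and Pfkp in 2, and Gpi1 and Eno1 in 1. Gapdh is on chromosome 6 from 125161715 to 125166467 on GRCm38. Its log fold changes in the authors' deposited table ran from 0.31 to 0.80, and those of Aldoa from 0.25 to 0.59. In cluster 4, Tpi1 was seen in 25.6% of syngeneic and 65.5% of allogeneic cells in the authors' deposited table, and Pgam1 in 52.2% and 78.1%. Ldhb was lower in cluster 1 (23.0% and 6.6% of cells) and the glucose transporter gene Slc2a3 in cluster 13 (64.3% and 3.8%), both from the authors' deposited table. The syngeneic shares of cluster 13 could all come from 14 cells, and its markers Alox5ap and Spi1 were seen in a far smaller share of allogeneic cells. The transporter genes Slc2a1 and Slc16a3 and the regulator gene Pfkfb3 had no call. The clusters with the most glycolysis calls were myeloid, with 8 in the macrophage-like cluster 8 and 7 in cluster 12, against 5 in cluster 4 and 4 in cluster 5. Of the other T cell clusters, 3 and 9 had 3 higher calls each, cluster 6 had 2, and clusters 0, 1 and 2 had 1 each. In cluster 8 T cell identity genes were called higher too, 10 of 11, and all 12 macrophage and monocyte genes lower. The list median was 0.35 at percentile 99.6. Without cluster 8 it was 0.28 at percentile 94.8, without cluster 10 it was 0.28 at percentile 90.1 and without cluster 11 it was 0.30 at percentile 96.5, so the list then no longer stood apart. In the T cell clusters alone the glycolysis list still stood apart.

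**Figure D3:**
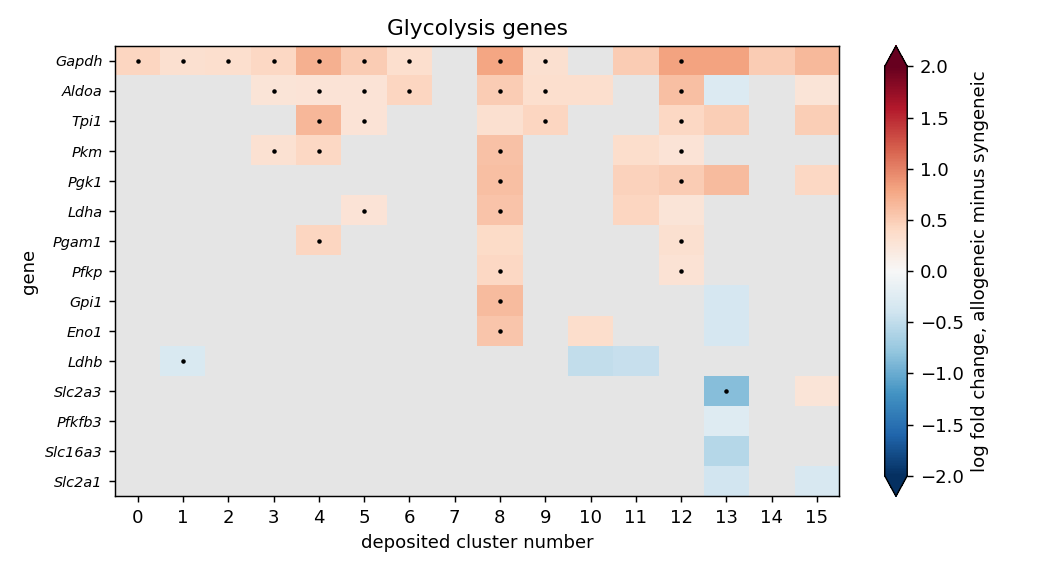
Colour gives the authors' log fold change, allogeneic minus syngeneic, of each listed glycolysis gene by cluster, with a dot for each call and grey where the gene is not listed. Gapdh is called higher in 10 clusters and Aldoa in 7.

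Other metabolic and growth lists gave the following counts. In oxidative phosphorylation 22 nuclear-encoded genes were called higher and 1 lower, with 51 pairs higher and 2 lower and a median of 0.33 at percentile 99.7. Of the higher pairs 18 were in cluster 12 and 15 in cluster 8, the cluster in which T cell genes rose and macrophage genes fell. Uqcrq, a subunit of complex III, was higher in 10 clusters and Atp5g3, of the ATP synthase, in 5. In the T cell clusters alone the list median was 0.26 at percentile 72.6 and did not stand apart, nor did it without cluster 13 (percentile 96.2). Transcripts of the mitochondrial genome went the other way, with 56 pairs lower and none higher among 13 genes, a median of -0.34 and percentile 4.18. Both mt-Atp8 and mt-Nd2 were lower in 8 clusters. Ribosomal protein genes had 148 pairs higher and 37 lower, with a median of 0.35 at percentile 100, yet 70 of the higher pairs were in cluster 8 and 19 in cluster 10, Rps29 was lower in 10 clusters, and in the T cell clusters alone the percentile was 57.0. Genes of pyruvate entry and the TCA cycle had 3 pairs higher and 7 lower (median -0.30, percentile 39.7). Genes linked to Myc and mTORC1 had 26 higher and 9 lower (median 0.10, percentile 92.7, and 99.8 without cluster 14). Among them Hif1a, a transcription factor gene of the low-oxygen response, was higher in 10 clusters and Odc1 in 7. Cell cycle genes had 30 pairs higher and 9 lower (median 0.50, percentile 100), with Mcm6 and Dut higher in 6 clusters and H2afz in 5. Cluster 5 held 10 of the higher pairs. Of the Mcm genes Mcm6 alone was called higher, and Mcm2 and Mcm3 were lower in cluster 6. Outside cluster 5, Mcm6 was seen in 18.5% of syngeneic and 48% of allogeneic cells in the authors' deposited table. Mcm3 was seen there in 17.5% and 20.4%, Mcm5 in 12.8% and 15.8% and Mcm7 in 17.9% and 19.3%. Over called pairs alone the percentile of the cell cycle list was 92.8, and in the T cell clusters alone 97.1. Adjusted over the list alone, pairs higher and lower were 78 and 13 for oxidative phosphorylation, 11 and 76 for mitochondrial transcripts, 232 and 58 for ribosomal proteins, 9 and 16 for the TCA cycle, 38 and 20 for Myc and mTORC1, and 51 and 10 for cell cycle.

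Cytotoxic and inhibitory receptor genes were among the groups most often higher. All 12 cytotoxic effector genes were called, with 62 pairs higher and 8 lower (median 0.43, percentile 100). Nkg7 and Cst7 were higher in 10 clusters and Gzmb and Gzmk in 7. Cluster 0 differed, with Gzmb, Prf1, Fasl, Klrg1 and Eomes lower there. So were 7 Treg genes, Foxp3 and Ikzf2 among them, and Klrg1 is also a leading marker of the Treg-like cluster 3. In cluster 5, Gzmk was seen in 10.0% of syngeneic and 69.7% of allogeneic cells in the authors' deposited table, and Gzma in 5.6% and 37.0%. Inhibitory receptor genes and Tox had 46 pairs higher and 5 lower (median 0.50, percentile 100), with Lag3 in 12 clusters, Tigit in 11, Pdcd1 in 9 and Tox in 7. In cluster 4, Pdcd1 was seen in 14.3% and 76.0% of cells and Tigit in 13.0% and 81.8%, from the authors' deposited table. Cytokine and chemokine genes had 51 higher and 13 lower (median 0.33, percentile 99.9), including Ccl5 in 13 clusters, and Ccl3, Ccl4 and Ifng in 7. Activation and costimulation genes had 46 higher and 22 lower (median 0.34, percentile 99.9), with Batf higher in 10 clusters and Tnfrsf4 in 9, though lower in cluster 0. The activation list no longer stood apart over called pairs alone (percentile 95.0), at detection of at least 25% (94.7), after centring (96.7) or in the T cell clusters alone (93.7), nor did the cytokine list with random lists also matched on listing (97.1). Some of these higher pairs were in cluster 8, in which T cell identity genes rose and macrophage genes fell. It held 8 cytotoxic, 5 inhibitory receptor and Tox, 7 cytokine and chemokine and 8 activation pairs. Adjusted over the list alone, pairs higher and lower were 70 and 10 for cytotoxic genes, 50 and 8 for inhibitory receptors and Tox, 61 and 24 for cytokines and chemokines, and 55 and 31 for activation and costimulation.

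Lists of helper and other T cell subsets gave the following counts. Th1 genes had 38 pairs higher and 22 lower (median 0.30, percentile 99.8), with Bhlhe40 higher in 8 clusters and Ccr2 lower in 8. The list did not stand apart in the T cell clusters alone (percentile 95.5) or with random lists also matched on the number of listing clusters (95.4). Th17 genes had 1 pair higher and 22 lower (median -0.57, percentile 0.19), led by Tmem176b in 8 clusters and Tmem176a in 7. It did not stand apart with means over clusters (percentile 3.61). Ccr6 was lower in 3 clusters and went from 23.7% to 0.6% of cells in cluster 2 in the authors' deposited table. Th2 genes had 1 pair higher and 11 lower (median -0.46, percentile 2.60, inside the central range), with Ccr4 lower in 6 clusters and Il4 in 3. Follicular helper genes had 29 higher and 4 lower (median 0.34, percentile 99.6), with Pdcd1 higher in 9 clusters and Sh2d1a in 6. Pdcd1 is also in the list of inhibitory receptors and Tox, so its calls count in both lists. Treg genes had 45 higher and 13 lower (median 0.30, percentile 99.8), although Tigit, Tnfrsf4 and Nrp1, which activated T cells also use, made many of these calls, and Nrp1 was lower in the Treg-like cluster 3. With the other matching the Treg percentile was 97.0 and the list did not stand apart. Naive and central memory genes had 5 higher and 46 lower (median -0.41, percentile 1.23), with Satb1 lower in 7 clusters and Foxp1 and Il7r in 6, though Il7r was higher in 2. That list ceased to stand apart when the mean over clusters was used (percentile 11.5) and when cluster 0, 2, 3, 4, 5, 7, 8, 9 or 12 was left out (percentiles 6.74, 2.93, 11.6, 11.6, 4.20, 11.9, 3.20, 3.94 and 4.33). Trafficking genes had 20 higher and 49 lower (median -0.34, percentile 7.42) and tissue residency genes 13 higher and 16 lower (median -0.30, percentile 43.2), among them Cd69, lower in 6 clusters. Adjusted over the list alone, pairs higher and lower were 44 and 31 for Th1, 2 and 30 for Th17, 1 and 15 for Th2, 32 and 6 for follicular helper, 52 and 18 for Treg, 8 and 57 for naive and central memory, 31 and 67 for trafficking, and 15 and 20 for tissue residency.

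Interferon genes did not move as one group. The interferon gamma response had 50 pairs higher and 27 lower (median 0.43, percentile 100). Psmb9, an immunoproteasome gene, was higher in 10 clusters, while the GTPase genes Irgm1, Gbp4 and Ifi47 were lower in 8, 7 and 7. In cluster 12 all 14 calls of this list were higher, Gbp4 and Ifi47 among them, and Ifi47 was also higher in cluster 7. The list had a percentile of 91.9 in the T cell clusters alone. The type I response had 25 higher and 24 lower (median -0.12, percentile 85.9), with Samd9l lower in 9 clusters. MHC genes had 38 higher and 11 lower (median 0.32, percentile 99.9), but in the T cell clusters alone the percentile was 86.3 and the list did not stand apart. H2-Q7 was higher in 14 clusters and its neighbour in the family, H2-Q6, lower in 8. Reads of such near-identical genes are uncertain. Cd74, the invariant chain of class II MHC, was called higher in 9 clusters and lower in cluster 13, where its log fold change was -1.11 while its share of cells went from 28.6% to 84.7% in the authors' deposited table. T cell receptor segments had 18 higher and 23 lower (median 0.19, percentile 99.0), and over called pairs alone the median was -0.37 at percentile 0.44, while without cluster 14 the percentile was 78.4 and in the T cell clusters alone 58.4. Trbv26 was higher in 9 clusters and Trbv13-2 lower in 5. Adjusted over the list alone, pairs higher and lower were 77 and 30 for interferon gamma, 40 and 36 for type I interferon, 60 and 20 for MHC and 27 and 30 for receptor segments.

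The following changes in single T cell clusters were in part called in other clusters too. In the Treg-like cluster 3, the authors' deposited table gave log fold changes of 2.34 for Ccl5, 2.23 for Cd74 and 2.10 for Ccl4. Cd74 was seen there in 7.9% of syngeneic and 84.9% of allogeneic cells, against 1.9% and 18.8% in cluster 2, per the authors' deposited table. Klf2 fell by 1.39, Itgb1 fell by 1.20 and S1pr1, an exit receptor gene of lymphocytes, fell by 1.06 in the authors' deposited table. Foxp3 and Ikzf2 were lower in the effector-like cluster 0, where Foxp3 was seen in 28.6% of syngeneic and 0.6% of allogeneic cells. Outside cluster 3, Foxp3 was seen in 4.1% and 1.5% of all other cells, also in the authors' deposited table. In the Th1-like cluster 1, Trbv13-2 went from 52.0% to 15.8% and Trbv26 from 0.7% to 43.8% of cells, per the authors' deposited table. Zbtb16 went from 34.5% to 0.3%, Il4 from 48.5% to 6.8% and Cd4 from 47.4% to 81.8% there, also in the authors' deposited table, so the mix of marker genes in cluster 1 differed between the groups. Ckb, encoding a creatine kinase, was lower in 9 clusters, with 73.6% and 12.4% of cells in cluster 5, and Art2b lower in 5 clusters, with 65.8% and 29.3% there, by the authors' deposited table. In the naive-like cluster 7, Igfbp4 fell by 1.43 and Ly6c1 had a log fold change of 1.49 in the authors' deposited table, though it was lower in 6 other clusters. Cluster 4 had 11 naive and central memory genes lower and none higher, with Ccr7 seen in 62.8% and 21.7% of cells in the authors' deposited table.

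Myeloid clusters changed as well. In the macrophage-like cluster 8 all 12 macrophage and monocyte genes were lower. Clec4f, a marker of Kupffer cells, the macrophages of the liver, was seen in 87.0% of syngeneic and 31.9% of allogeneic cells in the authors' deposited table, Vsig4 in 80.1% and 16.6%, and Fcna in 86.1% and 37.2%. C1qb was seen in 97.2% and 87.8%, while in cells outside the cluster it was seen in 0.9% and 6.0%, per the authors' deposited table. T cell genes were higher in the same cluster, 10 of 11 identity genes, with Cd3d at 19.4% and 54.8% and Cd4 at 19.0% and 50.2% of cells in the authors' deposited table. In cluster 12 the authors' deposited table gave 3.34 for Chil3, a gene of inflammatory monocytes, 2.85 for Ly6a and 2.43 for C1qb, which was seen in 4.0% and 44.8% of cells. Ace, Eno3 and Cd209a were the lowest calls there, with -1.29, -1.28 and -1.20 in the authors' deposited table. Chil3 went from 9.4% to 74.4%, Ace from 48% to 13.6% and Itgax from 50.5% to 27.2% of cluster 12 cells, also in the authors' deposited table. The mix of marker genes in cluster 12 thus differed between the groups. In the dendritic-like cluster 10, Klk1 was seen in 94.1% of syngeneic cells and listed at 0 in allogeneic cells, while Cd79a, a B cell gene, went from 7.2% to 56.2% in the authors' deposited table. Its marker Siglech went from 95.1% to 25% and the immunoglobulin genes Igkc and Iglc2 from 36.2% to 81.2% and from 18.3% to 68.8%, also in the authors' deposited table, so the mix of marker genes in cluster 10 differed between the groups. Its allogeneic shares could all come from 16 cells. The neutrophil-like cluster 15 had Slpi, Oasl2 and Gsr as its highest calls (1.75, 1.72 and 1.64) and Fos as its lowest (-1.91) in the authors' deposited table. In cluster 13 the ribosomal-repeat transcripts AY036118 and Gm42418 were highest (3.17 and 2.06), in the authors' deposited table, and Ccl9, Anxa1 and Ifitm1 were lowest (-2.37, -2.15 and -2.14). Its markers Alox5ap and Spi1 went from 85.7% to 16% and from 85.7% to 19.1% of cells. Cd3e went from 7.1% to 69.5% there without a call, so the mix of marker genes in cluster 13 differed too.

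**Figure D4:**
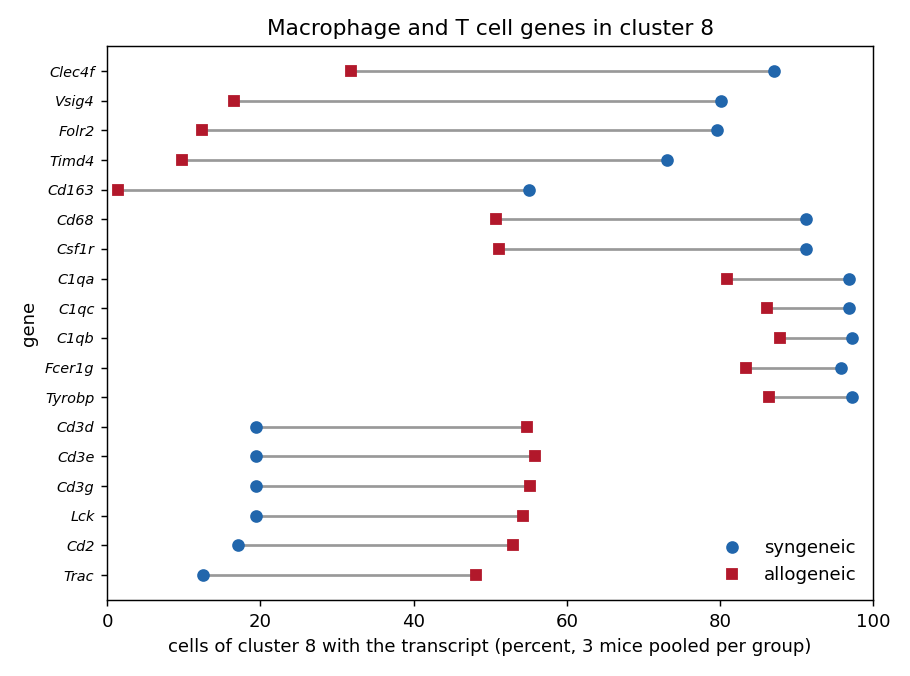
Points give the percentage of cluster 8 cells with each transcript, syngeneic as blue circles and allogeneic as red squares, with the cells of 3 mice pooled per group and no error known. Clec4f goes from 87.0% to 31.9%, while Cd3d goes from 19.4% to 54.8%.

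Lists of other cells and of sample handling gave the following counts. Over all clusters, macrophage and monocyte genes had 5 pairs higher and 15 lower (median -0.54, percentile 0.01), which without cluster 8 turned to a median of 1.20 at percentile 100. Dissociation stress genes had 11 higher and 41 lower (median -0.35, percentile 6.45), with Jun lower in 10 clusters, though higher in cluster 7, and Fos lower in 7, and T cell identity genes 28 higher and 12 lower (median 0.37, percentile 99.7, and 93.6 in the T cell clusters alone), with 10 of the higher pairs in cluster 8. Apoptosis and survival genes had 24 higher and 11 lower (median -0.29, percentile 53.2), with Bcl2 lower in 4 clusters. Hepatocyte genes had none higher and 6 lower, 5 of them in cluster 8 (median -0.49, percentile 0.57, but 3.89 without cluster 11 and 5.005 over called pairs), neutrophil genes 3 higher (median 0.41, percentile 99.9), in which S100a8 made 2 and Retnlg 1, and dendritic genes 18 higher and 7 lower (median -0.02, percentile 80.6). B and plasma cell genes had 9 higher and 3 lower (median 0.57, percentile 100), and without cluster 10 the percentile was 73.8. Endothelial genes had 3 lower, Pecam1, Cdh5 and Stab2 (median -0.64, percentile 0.69). NK genes had 4 lower in Klrk1 and Tyrobp, CD8 T cell genes 1 higher, Cd8b1 in cluster 5, and gamma delta and innate-like T cell genes 6 lower in Tcrg-C1 and Zbtb16, each with too few listed genes for a percentile. No erythroid gene was listed. Adjusted over the list alone, pairs higher and lower were 12 and 19 for macrophages, 15 and 56 for dissociation stress, 47 and 15 for T cell identity, 28 and 19 for apoptosis, 44 and 31 for strain-variable loci, and 24 and 10 for dendritic genes.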

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

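All tests of explanations in this part were chosen after the data were seen, and after the result they measure, except that the bound for the percentile of the glycolysis list with random lists also matched on the number of listing clusters was set before that percentile was seen.

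Cluster 16 lies outside every comparison above, because the authors' deposited table gives it values in syngeneic cells alone. It had 316 genes higher than in other syngeneic cells. Its leading genes were Cd79a, Cd79b, Iglc2 and Ms4a1, with Cd79a seen in 100% of its cells and 0.4% of others, and 9 of the B and plasma cell genes were among its markers. Whether allogeneic livers held such cells is not analysed here.

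Of the 216 genes that changed alike in at least 5 of the 10 T cell clusters, 84 were called in the myeloid cluster 12 and 132 were not. Of the 84, 76 kept their direction, which is 90.5%, against 132 of 171 genes, or 77.2%, that changed in fewer T cell clusters. The mix of marker genes in cluster 12 itself differed between the groups, and its part in these calls was not tested. Whether reads of near-identical copies play a part was not settled. Names of gene models, related sequences or pseudogenes made up 5.09% of the genes, against 3.88% of those called in fewer T cell clusters. A name does not measure shared reads and does not find every copy. A strain difference of the donor cells, or the distance of the Balb/c genome from the reference, may account for part of the set, but every allogeneic donor was B10.D2 and an exposure shared by all cells would look alike, so these cannot be told apart. Free RNA from T cells stays open as a part of the rise in cluster 12. Of the 117 genes of the set that were higher, 29 were listed in cluster 12, seen in at most 50% of its syngeneic cells and in fewer T cells than Cd3d, Cd3e and Cd3g. They rose there by a median of 38 points, and 19 of them by more than 23.2 points, the highest share of allogeneic cells with one of those 3 genes, which goes against such RNA as the source for those 19. The lower quartile was 15.8, however, 61 of the 117 genes are not listed in cluster 12, and the bound for this test was changed several times after its values were seen.

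In the macrophage-like cluster 8, T cell genes were higher and Kupffer cell genes lower. T cells joined to macrophages, or their free RNA, could account for the first part. C1qb was seen in 87.8% of allogeneic cells and the 10 listed T cell identity genes in a median of 52.2%, so at least 40.05% had C1qb beside a T cell gene of that share, while 6.0% of allogeneic cells outside the cluster had C1qb. Separate T cells without macrophage RNA placed in the cluster would thus not be enough. T cells that carried such RNA could lie inside the cluster, so the share outside it cannot rule them out. Macrophages that express T cell genes were not tested. Dilution by T cell RNA is argued against for the second part, because the median log fold change of 7 genes of resident macrophages, -1.72, lay below that of 10 general macrophage genes, -0.78, by a difference of -0.93, against an interquartile range of 0.40. Replacement by recruited monocyte-like cells stays open: 3 of 5 listed monocyte genes were higher, a count first taken as evidence, but T cell clusters list all 5, and restricted afterwards to genes that no T cell cluster lists the count was 0. Changed macrophages of the same origin were not tested.

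The higher glycolysis genes may have several sources. Reads shared with copies of Gapdh are argued against as the whole cause, since 25 pairs were higher and 2 lower without it. A larger share of cycling cells stays open: 9 glycolysis pairs were higher and none lower within the cell cycle clusters 5, 6 and 9, but Top2a was also higher in cluster 5, which the test had required not to happen. Clusters 6 and 9, with no call of Mki67 or Top2a, had 5 of these pairs, and in cluster 6 cell cycle genes were lower in 6 calls and higher in 2, which goes against this explanation there, while in cluster 9 they were higher in 4 calls and lower in none. A gene without a call may still differ, so it is not excluded. A shift shared by genes of like detection also stays open. The percentile among lists matched on detection and listing was 99.8, above the central 95%, but leaving out cluster 10, whose allogeneic shares can come from 16 cells, brought it to 93.9. That the percentile should hold without each cluster was asked only afterwards. Alloreactive activation and donor strain follow the same groups and were not tested.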

How the results depend on the processing

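The T cell clusters alone, the set without genes called alike in cluster 12 and a T cell cluster, and random lists also matched on the number of listing clusters were chosen after seeing the data. No paired analysis was possible because the tables pool the mice of a group, and for the same reason no replicate could be left out. Precision is limited by the cells behind a value, which may be as few as 16 allogeneic cells in cluster 10 and 14 syngeneic cells in cluster 13, and glycolysis changed its standing without cluster 10 (0.28). The cause of each change below was not tested, except where fewer pairs or clusters enter by construction.

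Of pairs called, 2599 higher and 3138 lower, a log fold change of at least 0.5 left 842 and 875, Benjamini-Hochberg adjustment gave 3951 and 6017, and the T cell clusters alone held 1718 and 1831. The share higher stayed below 50% under every alternative, between 39.6% and 49.0%. The 97 genes changed alike became 11 at 75% of the clusters and 216 in the T cell clusters. Of 3034 conserved markers, 1322 had a log fold change of at least 0.5 and 1742 a detection difference of at least 25 points in both groups.

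For list medians, those of the T cell clusters that no longer stood apart were 0.26 for oxidative phosphorylation, 0.30 for cell cycle, 0.29 for Th1, 0.29 for activation, 0.29 for interferon gamma, 0.30 for T cell identity, 0.26 for ribosomal proteins, -0.0048 for receptor segments and 0.28 for MHC. There -0.42 for Th2, -0.34 for trafficking, -0.36 for mitochondrial transcripts and 0.46 for dendritic genes came to stand apart. Without genes called alike in cluster 12 and a T cell cluster, glycolysis (-0.054), Th17 (-0.39) and Treg (-0.15) no longer did, but this filter takes members out because of their calls, so the losses follow from its construction and say nothing about those lists. With the other matching, Th1 (0.30), Treg (0.30) and cytokines (0.33) no longer did, while Th2 (-0.46) did. Over called pairs, cell cycle (0.30), activation (0.26) and hepatocyte genes (-0.44) were lost, mitochondrial transcripts (-0.36) were gained and receptor segments turned to -0.37. With means over clusters, Th17 (-0.42) and naive genes (-0.36) were lost and Th2 (-0.49) and dissociation stress (-0.41) gained. At detection of at least 25%, activation (0.26) was lost, and Th2 (-0.54), dissociation stress (-0.47) and mitochondrial transcripts (-0.34) were gained. After centring, activation (0.37) was lost, and Th2 (-0.22), trafficking (-0.11) and dissociation stress (-0.14) were gained. Unmatched random lists changed no list's standing.

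Leaving out each cluster gave medians from 0.28 to 0.35 for glycolysis, 0.31 to 0.34 for oxidative phosphorylation, -0.28 to 0.33 for Myc and mTORC1, -0.48 to -0.42 for Th2, -0.43 to -0.35 for naive genes, -0.35 to -0.32 for mitochondrial transcripts, -0.27 to 0.32 for receptor segments, -0.49 to -0.44 for hepatocyte genes, -0.54 to 1.20 for macrophage genes and -0.057 to 0.65 for B and plasma cell genes, and each of these lists changed its standing at least once. The 1.20 is the value without cluster 8, and the -0.057 that without cluster 10. Of the 48 alternatives for markers of single clusters 27 moved by over 1.5 times, and of the 216 for the number of clusters calling a named gene 24 did.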

Other observations

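The test of the hypothesis below was set before its genes were looked at, except that Cd160 was already in the list of inhibitory receptors and Tox. The genes that led to the hypothesis had been seen.

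Some genes used by natural killer T (NKT) cells, picked after their values were seen, were lower in allogeneic cells. In cluster 1 the authors' deposited table gave Zbtb16, the transcription factor gene of that lineage, in 34.5% of syngeneic and 0.3% of allogeneic cells, Txk in 68.1% and 8.9%, and Trbv13-2 in 52.0% and 15.8%. In the cell cycle cluster 5 Zbtb16 was seen in 28.0% and 0.1% of cells in the authors' deposited table, and no other T cell cluster called it. A hypothesis was that fewer NKT-type cells were among the allogeneic cells. It was tested on a list of 19 killer receptor and invariant receptor genes, of which at least Cd160 was in an earlier list. Of their called pairs 75% or more should then be lower. In the T cell clusters 1 pair was lower, Klrb1f in cluster 0, and 3 were higher, Klrc1 in clusters 2 and 4 and Cd160 in cluster 4. Without Cd160, fewer than the 4 called pairs that the test required were left. None of the 19 genes is listed in clusters 1 and 5, where Zbtb16 was lower, so the test says nothing about those clusters and the hypothesis of fewer NKT-type cells stays open. Among genes seen earlier, rows that go with it are Klrk1, lower in clusters 0 and 1, and Il4, which went from 48.5% to 6.8% of cells in cluster 1 in the authors' deposited table. Xcl1 was lower in clusters 0, 1, 5 and 6 but higher in cluster 4. Going the other way, the killer receptor gene Klrd1 was higher in the T cell clusters 0, 2, 4 and 9. It is not listed in clusters 1 and 5 either, so it says nothing about those. Klrg1 was lower in cluster 0 and higher in cluster 2.

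The chemokine gene Cxcl9 was called higher in clusters 8, 11 and 12, seen in 6.0% of syngeneic and 57.6% of allogeneic cells in cluster 8, in 1.5% and 49.6% in cluster 12, and listed at 0 in syngeneic and 21.2% of allogeneic cells in cluster 11, by the authors' deposited table. It was picked after its values were seen.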
